A study of Mus musculus with 4 samples.

How the data were processed

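RNA was measured by sequencing in 4 libraries of cells sorted from a spontaneous mouse model of pancreatic ductal adenocarcinoma on the C57BL/6 background. All cells carried FAP (fibroblast activation protein, a surface protease of stromal cells of tumours), and they were split by CD34, a surface sialomucin of endothelial, haematopoietic progenitor and some stromal cells. There were 2 libraries of FAP+ CD34+ cells and 2 of FAP+ CD34- cells, which the titles call biological replicates. Groups and replicate numbers were taken from the titles. No source used here says how many animals stood behind a library or whether a replicate number marks the same animals in both fractions. Per the labels' protocols, RNA was extracted with a Purelink kit and amplified with MessageAmp, a linear amplification from the poly(A) tail, so that amplified copies of a transcript are not independent molecules.

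The submitters' processing notes name Bowtie2, TopHat2, HTSeq and edgeR and the mouse build mm9; their versions, the gene annotation and the strand setting are not given in the sources used here. Whole-number counts of reads per gene were deposited for 22609 genes, not normalized. RPKM values (reads scaled to gene length and library total) were deposited for the same genes. Within a library, the ratio of the deposited counts to the deposited RPKM showed that the authors' scaling totals were not the sums of the counts; the count total over the scaling total was 65.0% of that in CD34- replicate 2 in CD34+ replicate 1, 84.3% in CD34+ replicate 2 and 94.8% in CD34- replicate 1. What the authors' totals held is not given in the sources used here. The deposited FPKM values, which the authors' name for the table calls bias-adjusted, cover 22558 genes. The deposited estimated counts of fragments go with these FPKM, need not be whole and were rounded here. Each deposited table also holds 14 further columns of values per sample that match no sample of this series, and they were not used here. The published T cell and FAP+ cell data sets that the design text names as comparators were not analysed here.

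Gene names in the tables are in lower case. Of the 22609 names, 20438 matched a current mouse symbol, 1981 an older symbol or synonym and 190 none, by name against tables of the GRCm38 assembly; since that is another build than mm9, no coordinates are given. Without the strand setting, reads of overlapping and antisense genes cannot be told apart. Counts of near-identical genes are uncertain, among them Hspa1a and Hspa1b, Ly6c1, C4b, Tnxb, and the class I genes H2-K1 and H2-D1.

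Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) after TMM scaling and filterByExpr, with the group as the only term, in all 4 libraries; 13875 genes were tested and p was adjusted by Benjamini-Hochberg at 0.05. Log2 fold changes are CD34+ over CD34-, the standard error is the fold change divided by the square root of F, and CPM are TMM-scaled counts, scaled to the library total as CPM, unless stated. All tests are two-sided. With 2 libraries per group the fit has 2 residual degrees of freedom, to which the moderation added 4.17, and an exact permutation test of a single value cannot go below p = 0.333. No such test was therefore run. Total counts were 10322354 and 13649942 in CD34+ replicates 1 and 2, and 13218444 and 14633561 in CD34- replicates 1 and 2. A gene with a count of 0 could hold up to 3 counts, which is 0.291, 0.220, 0.227 and 0.205 CPM in the same order, covering counting error only.

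There were 28 gene lists, covering fibroblast states, matrix, signalling and markers of other cell types that the gate could hold. The 24 lists with at least 3 tested genes were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction and compares them with no other genes. Members of a list were also adjusted over the list alone. Names in the text follow a rule: Fap, Cd34 and Cxcl12; up to 12 genes per direction past the threshold with a mean of at least 5 CPM and no overlap of the groups; if fewer than 5 passed in a direction, the 5 with the smallest p, given as values that did not pass; up to 4 genes of the smallest p per list, from 5 CPM; and the most abundant member of each list of another cell type. Other genes are named where a sentence says that they were chosen after their values were seen, and as members of lists. The lists, the rule, the groups, the tests and all alternatives but those said to be added were fixed before the data were examined.

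Alternatives were DESeq2 1.42.0, limma voom, edgeR's exact test, robust moderation and a fold threshold of 2 (glmTreat); other scalings; no filter or a filter of 1 CPM in 2 libraries; the replicate number as a block; and leaving out each library, where the lone library of a group is assumed to vary like the other group. Limma trend was also run on log2 of the deposited RPKM or FPKM plus a pseudocount of 1 or 0.1, for genes of at least 1 in 2 libraries, and for RPKM + 1 with no such filter. Fold changes on those scales understate the change of low genes. Added after seeing the data were edgeR on the rounded estimated counts of fragments, edgeR and camera on counts from which a background was taken, a percentile of each list's median among 10000 random lists matched on mean CPM, and shares of marker lists without each library. The background was the mean RPKM of 1005 of the 1117 olfactory receptor genes, leaving out those above the 0.9 quantile, scaled to each gene and library.

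The tests were tried on simulated counts in 5 simulations, with genes changed by known folds. Means were those of the real genes. The spread of each gene was the trend fitted to these libraries times a random factor, which raised it on average. Over the simulations together, 335 genes each were changed 2-fold and 4-fold and 330 genes 16-fold. The share of calls that are false and the share of changed genes recovered depend on these numbers and on the simulated spread. Neither need hold for the real counts. In the comparison of CD34+ with CD34- cells, over 13563 tested genes, the quasi-likelihood test recovered 62.1% of the genes changed 16-fold, 1.19% of those changed 4-fold and 0% of those changed 2-fold, and 6.70% of its calls were false. DESeq2 recovered 99.1%, 71.0% and 7.16%, with 47.6% of its calls false over 13874 genes, and the exact test 98.5%, 63.0% and 3.58% with 42.9% false. Limma voom recovered 61.5% of the 16-fold genes with 7.21% false, and the blocked fit 38.8% with 15.2% false. Camera called 0 of 115 unchanged lists and 1 list shifted 2-fold in 5 of 5 simulations. The simulated genes were drawn independently of each other, so this does not try camera on lists whose members are correlated. In the real counts the estimated correlation reached 0.877, for the list of MHC class I genes. Of 200 random lists of 11 genes, 10 lay outside the central 95% of matched random lists, and 50 of 50 lists shifted by 2 on the log2 scale were found. The genes of these lists too were drawn independently. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for library values, and matplotlib 3.10.9 for plots.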

Results

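Gene expression was compared between FAP+ CD34+ and FAP+ CD34- cells sorted from pancreatic ductal adenocarcinoma of mice, with 2 libraries of each. Total counts were 10322354 and 13649942 in CD34+ replicates 1 and 2 and 13218444 and 14633561 in CD34- replicates 1 and 2. The series concerns the chemokine CXCL12 made by FAP-expressing fibroblasts of this tumour in relation to blockade of PD-L1, and the comparison asks how the FAP+ cells differ by CD34. Values are TMM-scaled CPM as mean ± SD with n = 2 per group unless stated.

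The transcripts behind the sort were measured in every library. Cd34 was 146 and 291 CPM in the CD34+ libraries and 17.4 and 24.9 CPM in the CD34- libraries, a log2 fold change of 3.37 (SE 0.43). Adjusted over all 13875 tested genes this did not pass (adjusted p = 0.141, edgeR quasi-likelihood test), while adjusted over the list alone of the 2 sort markers Cd34 rose (adjusted p = 3.9e-04, edgeR). DESeq2, edgeR's exact test, edgeR without a filter and limma on log2 of the deposited RPKM called it over all genes, with adjusted p of 1.0e-11, 8.0e-09, 0.0013 and 0.015 (pseudocount 1). So did edgeR's quasi-likelihood test with the replicate number as a block (adjusted p = 0.015). Over every alternative its adjusted p lay between 1.0e-11 and 0.509. Fap, the protease that defined the gate, was 80.7 and 39.5 CPM in the CD34+ libraries and 135 and 141 CPM in the CD34- libraries. Its log2 fold change was -1.20 (SE 0.37, adjusted p = 0.230 over all genes, edgeR). Adjusted over the list alone Fap fell (adjusted p = 0.017, edgeR), a value equal to its unadjusted p. Cxcl12, the ligand of Cxcr4, was 177 and 367 CPM in the CD34+ libraries and 282 and 157 CPM in the CD34- libraries. The groups overlapped, and the log2 fold change of 0.31 (SE 0.45, adjusted p = 0.75, edgeR) was within its error. Its sign turned without CD34+ replicate 2 (-0.33) and without CD34- replicate 2 (-0.042), and on the log2 RPKM scale (-0.13).

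**Figure D1:**
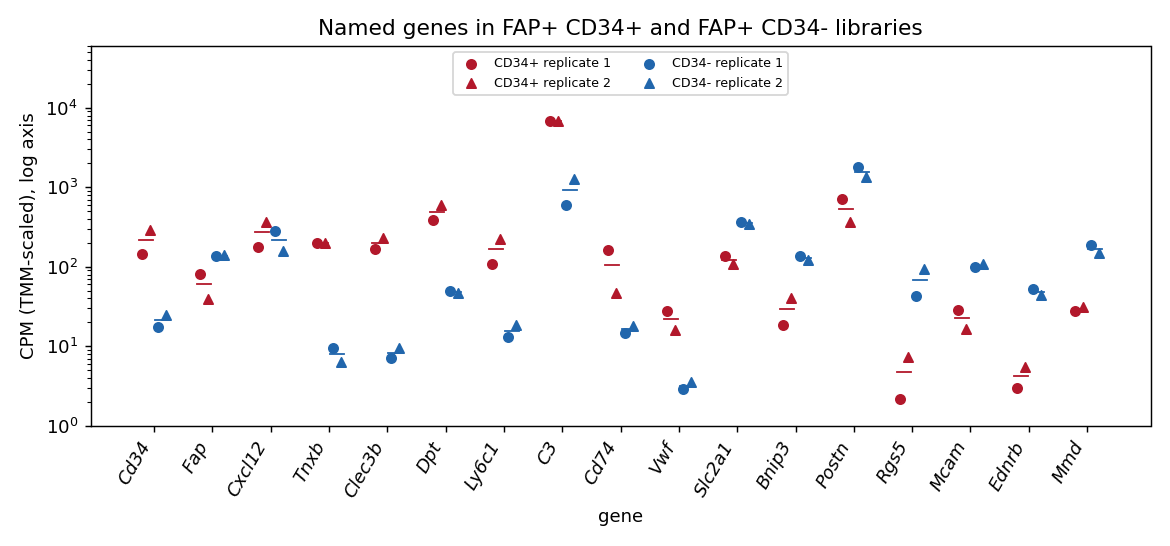
TMM-scaled CPM (log axis) of 17 named genes in each of the 4 libraries, red for FAP+ CD34+ and blue for FAP+ CD34-, with circles for replicate 1, triangles for replicate 2 and a bar at each group mean. Cd34 lies at 146 and 291 CPM in the CD34+ libraries against 17.4 and 24.9 CPM in the CD34- libraries, while the groups overlap for Cxcl12.

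Across all genes, the smallest p of those higher in CD34+ libraries belonged to Tnxb and Clec3b, which encode the matrix proteins tenascin-X and tetranectin. Tnxb was 199 ± 2.17 CPM in CD34+ and 7.95 ± 2.18 CPM in CD34- libraries (log2 fold change 4.65, SE 0.32), and Clec3b was 200 ± 44.4 against 8.29 ± 1.76 CPM (4.59, SE 0.34). Both had an adjusted p of 0.0522 (edgeR) and so missed the threshold, which both passed in many other settings, among them DESeq2 (adjusted p = 6.7e-32 and 9.0e-29), edgeR's exact test, edgeR without a filter, and limma on filtered log2 RPKM or FPKM. Over all alternatives the adjusted p of Tnxb lay between 6.7e-32 and 0.33 and that of Clec3b between 9.0e-29 and 0.354. Next came Lcn2, the siderophore-binding lipocalin (86.7 ± 8.77 against 9.27 ± 1.94 CPM), Dpt, encoding dermatopontin (493 ± 152 against 47.7 ± 1.81 CPM), and Selp, encoding P-selectin (24.7 ± 2.84 against 3.22 ± 0.179 CPM). In the other direction lay Mmd (29.2 ± 2.42 against 168 ± 28.0 CPM), the endothelin receptor gene Ednrb (4.25 ± 1.81 against 47.8 ± 5.91 CPM), the adrenergic receptor gene Adra2a (3.20 ± 0.0962 against 36.1 ± 13.9 CPM), Tnfrsf9, encoding 4-1BB (3.79 ± 0.520 against 28.1 ± 4.86 CPM), and D0H4S114 (96.8 ± 23.7 against 674 ± 62.8 CPM). None of these passed (adjusted p from 0.101 to 0.134, edgeR).

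At an adjusted p of 0.05, the edgeR quasi-likelihood test called 0 genes higher and 0 lower. Without adjustment 1361 genes lay higher and 923 lower at p of 0.05 (edgeR), where chance gives 694 in all on average. The groups did not overlap for 51.3% of genes, against 33.3% by chance on average. All genes share the same 4 libraries, so any difference between libraries can move many genes together. The excess over these averages is therefore no test of an effect of CD34. DESeq2 called 352 genes higher and 199 lower, and edgeR's exact test 470 and 206. In simulated counts 47.6% and 42.9% of their calls were false. That share depends on how many genes were changed in the simulation and on the spread it used, so it need not hold for these calls. Limma voom called 0 in each direction, and edgeR without a filter called 194 and 137. With the replicate number as a block, edgeR called 39 and 23. Sex-linked genes followed that number in both fractions, but no label says that it marks shared animals. On the authors' scales more genes were called lower than higher by limma, with 47 higher and 115 lower on log2 RPKM + 1 and 22 and 49 on log2 FPKM + 1, scales that shifted the median log2 fold change by -0.37 and -0.39. Among the 3357 genes under 5 CPM the median log2 fold change was 0.36, and among the 10518 others -0.09.

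The list of adventitial and progenitor-type fibroblast genes showed the largest shift of the 24 lists tested. All 13 members had a positive log2 fold change, with a median of 2.24, and 9 rose and 0 fell when adjusted over the list alone; 0 passed over all genes (edgeR). The risers were Tnxb, Clec3b, Dpt, Ly6c1 (168 ± 83.8 against 15.7 ± 3.83 CPM), the surface antigen gene Ly6a (Sca-1), Has1 (hyaluronan synthase), Sema3c, Efemp1 and Pi16. Dpp4, Cd248, Gli1 and Igf1 did not pass, with log2 fold changes from 0.69 to 1.13. The list ranked higher by camera (adjusted p = 1.8e-09, limma), and its adjusted p = 0.655 with an estimated correlation. Many lists share this last value, since the adjustment ties unadjusted p from 0.0508 (hypoxia and glycolysis) to 0.382 (interferon response, limma camera). The estimate of the correlation has 2 residual degrees of freedom. Endothelial, mesothelial and myeloid markers ranked higher in the same libraries (adjusted p = 0.0024, 0.010 and 0.015, limma camera; adjusted p = 0.655, 0.655 and 0.657 with an estimated correlation). Of the 14 general fibroblast markers 11 were positive (median 0.11), 0 passed and the list was not called (adjusted p = 0.162, limma camera). Their lowest p were those of Gsn (1607 ± 271 against 670 ± 111 CPM), Tcf21 (42.7 ± 6.24 against 16.3 ± 8.23 CPM), Pdpn (627 ± 184 against 282 ± 151 CPM) and Pdgfrb (315 ± 18.1 against 538 ± 45.0 CPM).

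Complement genes ranked higher in CD34+ cells (median 0.96, adjusted p = 0.010, limma camera; adjusted p = 0.655 with an estimated correlation), with 3 of 9 members risen when adjusted over the list alone. These were C3, the central component of the cascade (6788 ± 32.1 against 938 ± 469 CPM), C4b (2261 ± 170 against 332 ± 235 CPM) and Cfb, encoding factor B (2267 ± 1502 against 277 ± 136 CPM). C2 did not pass (515 ± 30.2 against 264 ± 131 CPM). Chemokines ranked higher as well (median 1.16, adjusted p = 0.010, limma camera; adjusted p = 0.655 with an estimated correlation). Of 16 tested, 3 rose over the list alone, namely the monocyte attractants Ccl2 (1293 ± 515 against 279 ± 192 CPM) and Ccl7 (1006 ± 108 against 319 ± 166 CPM) and the neutrophil attractant Cxcl5 (39.4 ± 1.48 against 21.3 ± 0.00381 CPM). Cx3cl1 lay the other way without passing (64.0 ± 4.71 against 173 ± 95.3 CPM). Cytokines and growth factors ranked higher (15 of 17 positive, median 0.98, adjusted p = 0.013, limma camera; adjusted p = 0.655 with an estimated correlation) with 0 members passing even over the list alone. Their lowest p were those of Csf1, the macrophage growth factor (1027 ± 637 against 225 ± 7.57 CPM), Csf3 (56.6 ± 28.3 against 7.84 ± 7.83 CPM), Fgf7 (62.0 ± 14.9 against 33.1 ± 4.06 CPM) and, lower, Tnfsf11 (3.45 ± 1.28 against 17.4 ± 13.3 CPM). Leaving out a library ended some of these calls: complement without CD34+ replicate 2 (adjusted p = 0.089) or CD34- replicate 1 (0.0503), chemokines without the same libraries (0.079 and 0.148), and cytokines without CD34+ replicate 1 (0.095) or CD34- replicate 1 (0.142), all by limma camera. With no filter on low counts all 3 calls ended (adjusted p = 0.0761, 0.103 and 0.14, limma camera). Markers of myeloid, endothelial and mesothelial cells ranked higher in the same libraries (adjusted p = 0.015, 0.0024 and 0.010, limma camera). They were not called with an estimated correlation (adjusted p = 0.657, 0.655 and 0.655, limma camera).

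Antigen presentation genes ranked higher in CD34+ cells. For MHC class II, 5 of 7 members rose over the list alone (median 1.93, adjusted p = 0.0040, limma camera; adjusted p = 0.655 with an estimated correlation). These were the invariant chain gene Cd74 (105 ± 82.2 against 16.3 ± 2.06 CPM), H2-Aa (55.3 ± 34.1 against 14.1 ± 3.54 CPM), H2-Eb1, H2-Ab1 and the transactivator gene Ciita. Cd74 was 163 CPM in CD34+ replicate 1 and 47.2 CPM in CD34+ replicate 2. For MHC class I, all 8 members were positive (median 0.61, adjusted p = 0.010, limma camera; adjusted p = 0.655 with an estimated correlation) and 0 passed over the list alone; H2-D1 was 599 ± 101 against 264 ± 38.2 CPM, H2-K1 764 ± 64.2 against 419 ± 108 CPM, and the immunoproteasome genes Psmb8 78.7 ± 0.368 against 45.8 ± 3.16 CPM and Psmb9 13.8 ± 1.13 against 5.93 ± 2.89 CPM. Interferon response genes ranked higher (12 of 14 positive, median 0.53, adjusted p = 0.028, limma camera; adjusted p = 0.655 with an estimated correlation), again with 0 passing over the list alone, among them Stat2 (42.3 ± 0.880 against 27.3 ± 0.907 CPM), Irf7 (74.1 ± 41.3 against 35.5 ± 5.15 CPM), Rsad2 and Usp18. The class I call ended without CD34+ replicate 2 (adjusted p = 0.079) or CD34- replicate 1 (0.288), and the interferon call without CD34+ replicate 1 (0.152) or CD34- replicate 1 (0.405, limma camera), and both ended with no filter on low counts (0.111 and 0.261). Markers of myeloid cells, which use class II, also ranked higher in CD34+ libraries, as did endothelial and mesothelial markers (adjusted p = 0.015, 0.0024 and 0.010, limma camera). With an estimated correlation these 3 lists were not called (adjusted p = 0.657, 0.655 and 0.655, limma camera). The myeloid call ended without CD34+ replicate 1 (adjusted p = 0.538) or CD34- replicate 2 (0.598).

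Hypoxia and glycolysis genes ranked lower in CD34+ cells (median -1.41, adjusted p = 4.9e-04, limma camera; adjusted p = 0.655 with an estimated correlation). Of 11 tested, 6 fell and 1 rose when adjusted over the list alone. Those that fell were the glucose transporter gene Slc2a1 (122 ± 19.1 against 351 ± 14.1 CPM), the pyruvate dehydrogenase kinase gene Pdk1 (14.7 ± 1.34 against 44.1 ± 9.32 CPM), the collagen prolyl hydroxylase gene P4ha1 (159 ± 27.2 against 460 ± 38.4 CPM), the mitophagy receptor gene Bnip3 (29.5 ± 15.8 against 131 ± 11.4 CPM), Pgk1 and Egln3, and Ndrg1 rose (log2 fold change 1.38). Collagens and other matrix genes ranked lower (16 of 22 negative, median -0.53, adjusted p = 0.012, limma camera; adjusted p = 0.655 with an estimated correlation), with 0 passing over the list alone. Postn, encoding periostin, was 538 ± 236 against 1577 ± 311 CPM, Col5a2 1748 ± 136 against 3351 ± 254 CPM, Col6a3 353 ± 114 against 716 ± 208 CPM and Col6a1 946 ± 32.0 against 1669 ± 283 CPM. Without CD34+ replicate 2 the matrix call ended (adjusted p = 0.132, limma camera). The pericyte markers Rgs5, Mcam, Ndufa4l2 and Higd1b fell over their list alone, with log2 fold changes of -3.82, -2.20, -1.71 and -3.73. Endothelial, mesothelial and myeloid markers ranked higher in CD34+ libraries (adjusted p = 0.0024, 0.010 and 0.015, limma camera), but not with an estimated correlation (adjusted p = 0.655, 0.655 and 0.657).

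**Figure D2:**
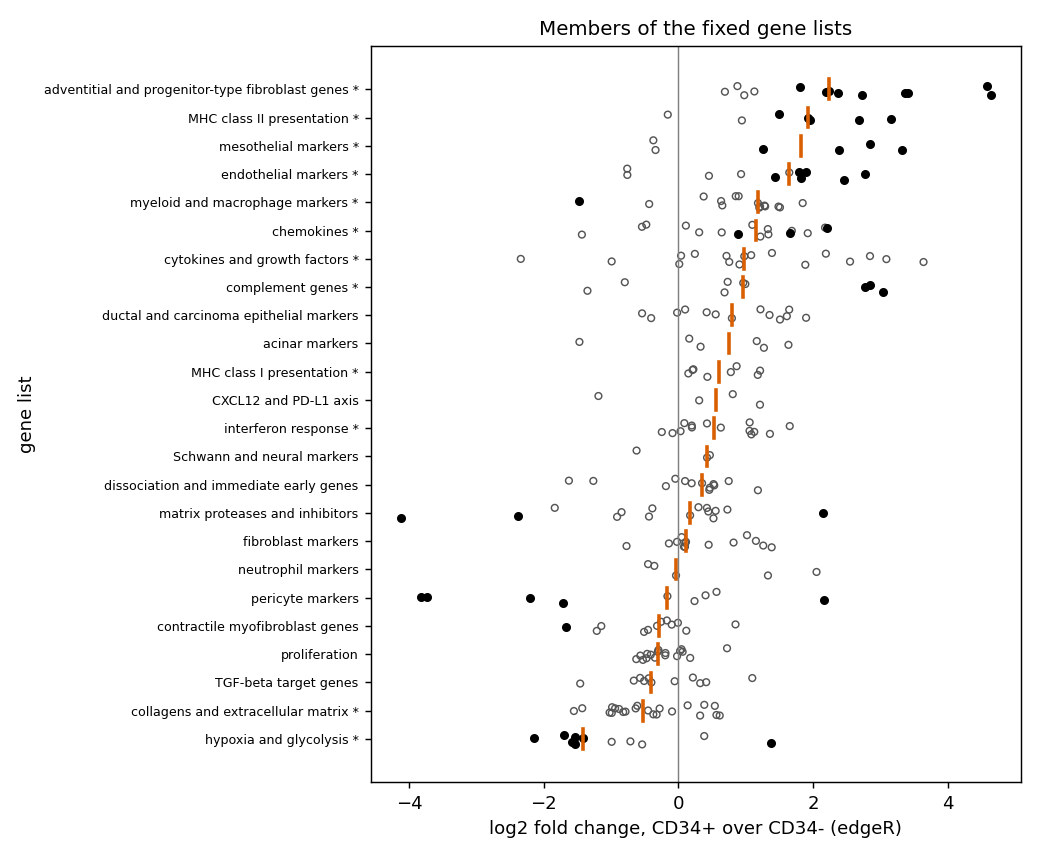
Log2 fold change (CD34+ over CD34-, edgeR) of each tested member of the 24 lists, 1 point per gene, with filled points for genes whose p adjusted over the list alone was under 0.05, an orange bar at the list median and an asterisk for lists past the camera threshold. The adventitial list has the highest median (2.24) and the hypoxia and glycolysis list the lowest (-1.41).

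Pericyte markers moved both ways and contractile genes were mostly negative, and neither list was called. Of 9 pericyte markers 4 fell and 1 rose over the list alone (edgeR). Rgs5, a regulator of G protein signalling of mural cells (4.73 ± 3.61 against 68.3 ± 35.5 CPM), Mcam (22.5 ± 8.58 against 103 ± 6.53 CPM), Ndufa4l2 (19 ± 7.59 against 62.5 ± 21.6 CPM) and Higd1b fell, and the aminopeptidase gene Anpep rose (39.4 ± 10.8 against 8.76 ± 0.189 CPM). The most abundant member, Cspg4, was 150 ± 139 against 168 ± 50.6 CPM. For the list adjusted p = 0.079 (median -0.16, limma camera). Of 12 contractile genes 10 were negative and 1, Actg2, fell over the list alone (14.3 ± 5.52 against 45.3 ± 1.89 CPM; list median -0.29, adjusted p = 0.052, limma camera). Cnn1 was 4.87 ± 0.813 against 11.3 ± 0.171 CPM, Myh11 7.97 ± 0.769 against 17.6 ± 5.69 CPM and Tpm1 557 ± 129 against 792 ± 202 CPM. The contractile list passed without CD34+ replicate 1 (adjusted p = 0.0043) or CD34- replicate 1 (0.021), and the pericyte list without CD34- replicate 1 (0.030, limma camera). With no filter on low counts both passed (0.00976 and 0.0298), and with scaling by library size the contractile list did (0.0415). Among 15 matrix proteases and inhibitors, the collagenase gene Mmp13 (14.6 ± 2.44 against 254 ± 250 CPM) and the gelatinase gene Mmp9 (13.5 ± 6.88 against 70.1 ± 37.5 CPM) fell and the aggrecanase gene Adamts5 rose (567 ± 218 against 127 ± 89.8 CPM) over the list alone, while Mmp19 did not pass (47.0 ± 12.8 against 84.4 ± 21.6 CPM). That list had a median of 0.18 but a mean of -0.37, and its test pointed lower (adjusted p = 0.542, limma camera); without CD34- replicate 1 it passed (0.030).

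For 4 further lists 0 members passed over the list alone and the list was not called. TGF-beta targets had a median of -0.40 (adjusted p = 0.394, limma camera), with Tgfbi at 80.5 ± 40.8 against 221 ± 50.7 CPM, Ctgf at 1752 ± 334 against 2772 ± 812 CPM and Tgfb3 at 255 ± 1.96 against 336 ± 89.5 CPM; without CD34- replicate 1 they ranked lower (adjusted p = 0.0499). Proliferation genes had a median of -0.30 (adjusted p = 0.458, limma camera), with Tyms at 31.5 ± 1.44 against 19 ± 3.38 CPM and Rrm2, Ccna2 and Cdk1 overlapping between groups; without CD34- replicate 2 the list ranked lower (adjusted p = 0.0015). Immediate early and heat shock genes had a median of 0.35 (adjusted p = 0.542, limma camera), with Fosb at 2671 ± 157 against 1176 ± 674 CPM, Zfp36 at 1165 ± 99.7 against 693 ± 267 CPM, Hspa1a at 419 ± 157 against 1005 ± 379 CPM and Hspa1b at 297 ± 156 against 916 ± 379 CPM. The CXCL12 and PD-L1 axis had 4 tested genes with a median of 0.56 (adjusted p = 0.542, limma camera). Besides Cxcl12 they were Cd274, encoding PD-L1 (7.04 ± 2.23 against 4.0 ± 1.08 CPM), Cxcr4 (5.31 ± 2.57 against 12 ± 6.44 CPM) and the scavenging receptor gene Cxcr7 (318 ± 176 against 137 ± 112 CPM).

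Within each library Cxcl12 was ranked among the 17 chemokine genes by the deposited RPKM. Its rank was 9 and 9 in the CD34+ libraries and 7 and 10 in the CD34- libraries, at 17.1, 47.4, 42.8 and 23.0 RPKM. Cxcl1 was first in all 4 libraries, with a mean of 1661 ± 718 RPKM (SD, n = 4 libraries). By RPKM, Ccl2, Ccl7, Cxcl2, Cxcl14 and Ccl11 also lay above Cxcl12 in all 4 libraries. By CPM, Cxcl14 did so in 4 libraries, Ccl2 and Ccl7 in 3 each, Cxcl2 in 2 and Ccl11 in 0. The rank depended on the unit: its median was 9 by RPKM, 7 by the authors' bias-adjusted FPKM and 5.5 by CPM, which takes no account of gene length. Ranks compare genes within a library and carry no test.

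Each list of markers of another cell type was a smaller share of all counts than the general fibroblast markers. Those 14 genes made up 1.98 ± 0.43% of counts in CD34+ and 1.55 ± 0.13% in CD34- libraries. The 2 sort markers, Fap and Cd34, made up 0.0277 ± 0.0078% and 0.0160 ± 7.9e-05%, less than epithelial, pericyte or myeloid markers did. A share of counts is not a share of cells. Epithelial markers made up 0.0830 ± 0.0253% of counts in CD34+ and 0.0708 ± 0.0249% in CD34- libraries, pericyte markers 0.0393 ± 0.0066% and 0.0536 ± 0.0053%, and myeloid markers 0.0281 ± 0.0117% and 0.0181 ± 0.0060% (SD, n = 2 each). In the same order, mesothelial markers made up 0.0205 ± 0.0086% and 0.0118 ± 0.0027%, endothelial markers 0.0118 ± 0.0030% and 0.0059 ± 3.8e-04%, and acinar markers 0.0045 ± 8.2e-04% and 0.0026 ± 0.0011%. Neutrophil markers made up 0.0026 ± 4.9e-04% and 0.0020 ± 5.3e-04%, Schwann markers 0.0021 ± 2.7e-04% and 0.0023 ± 2.0e-04%, and erythroid markers 2.1e-04 ± 6.4e-05% and 1.1e-04 ± 7.4e-05%. Lymphocyte markers made up 0.0017 ± 0.0013% and 5.3e-04 ± 4.8e-05%, and islet markers 5.2e-04 ± 4.1e-04% and 8.2e-05 ± 2.0e-05%. These last lists rested on CD34+ replicate 1, without which the mean over the libraries went from 0.0011% to 6.3e-04% for lymphocyte markers and from 3.0e-04% to 1.3e-04% for islet markers. The shares carry no test. The most abundant epithelial marker was Krt8 (214 ± 14.8 against 199 ± 72.0 CPM) and the most abundant myeloid marker Cd14 (85.5 ± 44.6 against 54.3 ± 25.5 CPM).

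Several of these lists moved with CD34. Endothelial markers ranked higher in CD34+ libraries (median 1.65, adjusted p = 0.0024, limma camera; adjusted p = 0.655 with an estimated correlation), and 6 of 11 rose over the list alone, among them Vwf, encoding von Willebrand factor (22 ± 8.12 against 3.22 ± 0.482 CPM), Pecam1 (13.9 ± 3.17 against 2.5 ± 1.5 CPM), Plvap (16.4 ± 5.13 against 4.73 ± 1.55 CPM) and Egfl7 (12.3 ± 7.88 against 3.47 ± 0.885 CPM). Emcn and Esam lay the other way (log2 fold change -0.76 each). Mesothelial markers ranked higher (median 1.83, adjusted p = 0.010, limma camera; adjusted p = 0.655 with an estimated correlation) with 4 of 6 risen over the list alone, Wt1 (165 ± 64.6 against 68.7 ± 19.6 CPM), Upk3b, Lrrn4 and Gpm6a, while Msln (32.3 ± 26.3 against 41.7 ± 41.8 CPM) and Upk1b (4.45 ± 2.66 against 5.67 ± 3.04 CPM) overlapped between groups. Myeloid markers ranked higher (median 1.18, adjusted p = 0.015, limma camera; adjusted p = 0.657 with an estimated correlation), although the single member that passed over the list alone, the Fc receptor gene Fcgr3, fell (11.1 ± 2.93 against 30.7 ± 5.14 CPM). Lyz2 was 74.1 ± 2.25 against 39.8 ± 5.32 CPM, and Laptm5 and C1qb overlapped between groups. The myeloid call ended without CD34+ replicate 1 (adjusted p = 0.538) or CD34- replicate 2 (0.598, limma camera). With no filter on low counts the mesothelial and myeloid calls ended (0.0596 and 0.129).

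Epithelial markers were not called (10 of 13 positive, median 0.80, adjusted p = 0.059, limma camera), but were without CD34+ replicate 2 (0.0061) or with background-subtracted counts (0.0402). Muc1 was 38.3 ± 6.13 against 22.1 ± 0.110 CPM, Tff2 29.7 ± 13.0 against 9.45 ± 7.47 CPM, Cldn7 12.9 ± 12.6 against 3.43 ± 0.278 CPM and Cldn4 54.0 ± 54.4 against 17.6 ± 2.86 CPM, and 0 passed over the list alone. Acinar markers (median 0.75, adjusted p = 0.395), neutrophil markers (median -0.034 with a mean of 0.51 and a test pointing higher, adjusted p = 0.304) and Schwann markers (median 0.43, adjusted p = 0.915) were not called by limma camera, and 0 of their members passed. In these lists Reg1 was 13.5 ± 11.1 against 4.33 ± 0.424 CPM, Cpa1 10.3 ± 11.9 against 4.60 ± 2.95 CPM, Ctrb1 9.21 ± 6.02 against 7.28 ± 6.68 CPM, Cela1 6.85 ± 0.720 against 6.12 ± 1.92 CPM, Cxcr2 8.84 ± 5.29 against 2.11 ± 0.774 CPM, Mmp8 9.12 ± 1.67 against 9.32 ± 4.03 CPM, S100b 8.99 ± 3.24 against 13.8 ± 4.10 CPM and Ngfr 10.5 ± 5.38 against 7.64 ± 3.79 CPM. Lymphocyte, islet and erythroid markers had 2, 1 and 1 tested genes, too few for a list test. The islet gene Ppy had a log2 fold change of 3.24 and an unadjusted p under 0.05 (edgeR), as 2284 genes had. In a list of 1 tested gene the adjustment changes nothing, and Ppy did not pass over all genes. The tested lymphocyte and erythroid genes did not pass.

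The libraries differed beyond their groups. Across genes, log2 CPM correlated at 0.977 between the CD34+ replicates and 0.986 between the CD34- replicates, and at 0.964 to 0.983 between groups, so CD34+ replicate 2 lay closer to CD34- replicate 2 (0.983) than to CD34+ replicate 1 (Pearson correlations across genes, which are not independent replicates). Genes with at least 1 count numbered 19627 and 19613 in the CD34+ libraries and 17452 and 16818 in the CD34- libraries. Olfactory receptor genes, which are silent in most tissues, had a count for 571 and 573 of 1117 genes in the CD34+ libraries and for 157 and 115 in the CD34- libraries. Their mean background was 0.0362 and 0.0354 RPKM against 0.0068 and 0.0048 RPKM. Xist, transcribed from the inactive X chromosome, had 2399 and 2160 counts in replicate 1 of the CD34+ and CD34- cells and 36 and 4 counts in replicate 2, and the Y-linked Ddx3y had 358 and 511 against 2085 and 2292 counts, so that sex-linked genes followed the replicate number and not CD34.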

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

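The alternatives with estimated fragments and with background-subtracted counts, the percentiles among random lists matched on CPM, and the shares of marker lists without single libraries, were chosen after seeing the data; all others were planned. The count of 0 genes higher and 0 lower was also given by edgeR with DESeq2's size factors, robust moderation and a fold threshold, by limma voom, by limma on log2 RPKM + 1 without a filter, on estimated fragments and without each library in turn. Other settings gave more calls (higher and lower): library size only 2 and 0, upper quartile 2 and 0, 1 CPM in 2 libraries 2 and 0, background-subtracted counts 2 and 0, no filter 194 and 137, DESeq2 352 and 199, the exact test 470 and 206, log2 RPKM + 1 47 and 115, log2 RPKM + 0.1 34 and 88, log2 FPKM + 1 22 and 49, and log2 FPKM + 0.1 16 and 20. The 2 calls of library size only, upper quartile, the 1 CPM filter and background subtraction were Tnxb and Clec3b. Of the 331 genes called without a filter, 319 were also called by DESeq2. The deposited RPKM and FPKM moved the median log2 fold change of the tested genes by -0.37 to -0.46. For RPKM this goes with scaling totals that are not the sums of counts. The cause of the other differences was not tested.

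With the replicate number as a block, edgeR called 39 genes higher and 23 lower, and the lists 10 and 2 as without it. The difference between replicates 1 and 2 in the CD34+ cells correlated at 0.241 with that in the CD34- cells across 13875 genes. No label says that a number marks shared animals, and there are 2 numbers only, so pairing was not assumed.

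Cd34 kept its sign throughout and passed with no filter (3.29), DESeq2 (3.33), the exact test (3.37), the replicate block (3.31), log2 RPKM + 1 (2.72) and log2 RPKM + 0.1 (2.88); Fap passed on log2 RPKM + 1 (-1.63). Cxcl12 reversed on log2 RPKM + 1 (-0.13, with and without a filter) and + 0.1 (-0.14), and ranged from -0.33 to 0.76 without single libraries. Of 2262 values of the 103 named genes under the alternatives, 1990 kept their side and sign, 231 passed where the reported test did not, and 41 reversed, none of them called. Besides Cxcl12, these were Mmp8 (upper quartile 0.060, voom 0.0077, replicate block 0.017, estimated fragments 0.23), Krt8 (log2 RPKM + 1 -0.26, with and without a filter, RPKM + 0.1 -0.27, FPKM + 1 -0.46, FPKM + 0.1 -0.46, fragments -0.026), Cela1 (RPKM + 1 -0.18, with and without a filter, RPKM + 0.1 -0.22, FPKM + 1 -0.34, FPKM + 0.1 -0.40), Ctrb1 (FPKM + 1 -0.17, FPKM + 0.1 -0.15) and Ngfr (FPKM + 1 -0.076, FPKM + 0.1 -0.13). Without single libraries the ranges were Mmp8 -0.46 to 0.49, Krt8 -0.22 to 0.49, Cela1 -0.12 to 0.48, Ctrb1 -0.56 to 1.79, Ngfr -0.21 to 1.1, Cd14 -0.018 to 1.19, Cldn4 -0.19 to 2.37, Upk1b -1.16 to 0.36, Cspg4 -1.71 to 0.54, Cpa1 -1.31 to 2.05, Msln -1.61 to 1.37 and Ccna2 -1.08 to 0.018. The cause was not tested.

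Of the lists, 10 ranked higher and 2 lower by camera. An estimated correlation left 0 and 0, as did fry, with 2 residual degrees of freedom for the estimate. Without a filter 3 ranked higher and 4 lower, and without single libraries 5 to 9 higher and 1 to 6 lower. The adventitial, MHC class II, endothelial and hypoxia lists were called in every setting but the estimated correlation and fry. Among random lists matched on mean CPM, the medians of the 10 lists called higher lay at or above percentile 99.0 and those of both lists called lower at percentile 0. The random lists were drawn gene by gene from the same fold changes and take no account of correlation within a list. They are therefore no check on the preset correlation of camera. The median rank of Cxcl12 among chemokines moved from 9 to 7 by FPKM and 5.5 by CPM. As shares of RPKM and FPKM, the means of marker lists over the 4 libraries moved to 0.0991% and 0.112% (epithelial), 0.0371% and 0.0334% (myeloid), 0.0037% and 0.0037% (neutrophil), 0.0077% and 0.0072% (acinar), 8.4e-04% and 9.0e-04% (islet), 0.0322% and 0.0299% (pericyte), and as shares of FPKM to 0.0085% (mesothelial), 0.0080% (erythroid) and 0.0015% (Schwann). Depth limits genes under 0.205 to 0.291 CPM, depending on the library, where 3 counts or fewer stand behind a value.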

Other observations

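The tests of library depth, of low expression, of background subtraction and of the replicate numbers were chosen after the data were seen, as were the 3 added gene lists, adjusted together, and the genes named singly here (Spp1, Dmp1, Smoc1, Enpp1, Dlk1, Cdkn1c, Igf2, Xist, Depdc5 and Malat1).

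Of the genes named here, 4 have roles in mineralised matrix, and none passed over all genes. Spp1, encoding osteopontin, was 1828 and 2043 CPM in the CD34+ libraries and 14146 and 12374 CPM in the CD34- libraries (log2 fold change -2.78, SE 0.43, adjusted p = 0.159, edgeR). Dmp1, encoding dentin matrix protein, was 0.684 ± 0.268 against 12.8 ± 3.40 CPM, Smoc1 2.66 ± 0.258 against 19.3 ± 5.40 CPM, and Enpp1, which makes pyrophosphate, 46.8 ± 10.8 against 213 ± 55.9 CPM (SD, n = 2 each). A list of 10 other mineralisation genes was split. Its median log2 fold change was -0.032 (adjusted p = 0.986, limma camera). Of its members 5 were positive, among them Omd (23.5 and 12.5 against 4.53 and 3.20 CPM), and 5 negative, among them Col10a1 (8.51 and 6.34 against 30.5 and 291 CPM, where CD34- replicate 2 carried most of the difference). Whether a part of this programme is lower in CD34+ cells stays open.

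The imprinted genes Dlk1 and Cdkn1c had positive log2 fold changes that did not pass over all genes. Dlk1 was 72.6 and 32.0 CPM against 0.863 and 2.06 CPM (log2 fold change 5.15, SE 0.61, adjusted p = 0.134, edgeR), and Cdkn1c, encoding a cell cycle inhibitor, 233 and 283 against 30.3 and 53.7 CPM (2.62, SE 0.36, adjusted p = 0.157, edgeR). Igf2 was 100.5 and 759 against 10.4 and 583 CPM in replicates 1 and 2, so that the groups overlapped. A hypothesis was that imprinted genes are higher as a class. A list of 13 others was drawn up after the genes above were seen but before the values of its members were. Its median log2 fold change was 0.39 with 10 positive (adjusted p = 0.029, limma camera). This goes with the hypothesis, but the adjusted p was 0.205 with an estimated correlation (limma camera). H19 and Gnas lay at -0.041 and -0.038 and Igf2r at -0.28, so the class did not move as a whole.

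Endothelial markers ranked higher in CD34+ libraries and the background at silent genes was higher there as well. Taking the background off the counts, which moved 2296 genes by more than 0.1 on the log2 scale in some library, left the endothelial median at 1.60 from 1.65 and the list called (adjusted p = 0.0016, limma camera), which argues against background reads as the whole cause; the lower bootstrap bound over genes, 0.47, lay above the 0.41 that this cause would need the median to fall under, but below the limits for its exclusion set before the test (0.5 among them), which the median itself met. Low expression as such is argued against too, since the median lay at percentile 100 of random lists matched on CPM, whose own median was -0.050. A second list of 19 endothelial genes had a median of 0.88 with 15 positive (adjusted p = 1.2e-04, limma camera, and 0.14 with an estimated correlation). Many of its members lay under 5 CPM, where the median log2 fold change of all tested genes was 0.36. Neither the matching on CPM nor the background subtraction was applied to this second list. Endothelial cells in the CD34+ fraction may contribute, since CD34 is on their surface, although the FAP gate would remove those without FAP. The most abundant gene of that list, Eng, was 249 and 267 against 211 and 316 CPM, Aplnr (-1.41) and Lyve1 (-1.35) lay the other way, and expression of these genes by CD34+ stromal cells stays open as a biological explanation that was not tested.

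Olfactory receptor genes with a count were more numerous in CD34+ libraries. Depth does not account for this, since after thinning to 10322354 counts the lower CD34+ library still held 3.87 times as many as the higher CD34- library (571 and 472 against 122 and 82). Sharing of reads between paralogs is argued against by 40 single-copy genes of other organs, of which 1.91 times as many had a count in thinned CD34+ libraries. Of the candidate sources left, genomic DNA or unspliced RNA carried into the libraries could not be measured from gene counts. No biological explanation was tested.

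Xist and Y-linked genes split by replicate number. The log2 ratio of Xist in replicate 1 over replicate 2 was 6.46 in CD34+ and 9.22 in CD34- cells. The shared sign restates the split itself, so it is no separate test of a crossing of the numbers in 1 fraction. Without 5 sex-linked genes, Xist and Y-linked genes among them, the differences between replicates in both fractions still correlated at 0.234 across 13870 genes. Other genes of the X chromosome were not left out. The same animals, the same day or a like mix of sexes behind both fractions of a number could each give this correlation. These cannot be separated here. Replicate 1 held Y-linked counts besides Xist in both fractions, which a pool of female and male cells would give, an idea that was not tested.

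Depdc5 had 10609 counts in CD34+ replicate 1 and 615, 372 and 457 in the others. The nuclear RNA Malat1 was 9844 CPM in that library and 2726, 2611 and 1390 CPM in the others.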
